A study of Homo sapiens with 6 samples.

How the data were processed

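Total RNA of 6 subcutaneous A549 tumours, 3 from cells carrying an empty lentiviral vector and 3 from cells overexpressing HIF1A-AS3, was sequenced as 1 library per tumour, per the labels' protocols. A549 is a human lung adenocarcinoma line, and the hosts were BALB/c nude mice, which lack a thymus. The submitters' processing notes list the mouse genome build mm10, Trimmomatic 0.39, HISAT2 2.2.1, featureCounts 2.0.6, DESeq2 and edgeR, without a role or order for each. The name of the deposited table points to salmon, a transcript quantifier that those notes do not list, and its version and annotation release are not given in the sources used here.

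The authors deposited a single table of estimated counts per gene, with 1 column per tumour and no normalization, per the file header. Each of its 6 columns was matched to a tumour by its name, and no column was left unmatched. All 77134 rows carried versioned Ensembl gene IDs with the mouse prefix ENSMUSG. The rows therefore describe transcripts assigned to mouse genes: RNA of the host cells in the tumour, plus any human RNA similar enough to be counted on a mouse gene. HIF1A-AS3 is a human RNA and was not analysed here, so the labels could not be checked against the overexpressed RNA.

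The table pairs no ID with a gene name, and 0 of its IDs matched the human name tables used here. Named genes, gene positions and the 44 gene lists drawn up by symbol before the data were examined (macrophage activation, HIF target genes, host cell types, RNA quality and others) were therefore not analysed. The rule for named genes, also fixed before the data were examined, took the genes with the largest fold change past the threshold and left out genes known only by an ID, so it named none. The 4 genes given by ID were chosen after their values were seen: both genes past the threshold, and in each direction the gene with the smallest p among those above 0 in every library.

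Among the resources used here, the only gene grouping by mouse Ensembl ID was the cell cycle marker set of the R package scran 1.30.0. It holds pairs of genes whose order of expression marks a phase. This choice was made after the data were examined. Each of its 667 genes was assigned to the phase (G1, S or G2M) in which it was most often the higher rather than the lower member of a pair. Of these genes, 666 were present as rows and 595 passed the filter on low counts.

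Estimated counts were rounded to whole numbers and analysed in R 4.3.3. Low rows were removed with edgeR 4.0.16's filterByExpr at its defaults, which left 12637 genes holding 99.5% of all counts, and 51637 rows were at 0 in every library. Libraries were scaled with TMM, and the groups were compared with edgeR's robust quasi-likelihood F-test (model with group only, Benjamini-Hochberg adjusted p below 0.05). Standard errors of log2 fold changes were taken as the fold change divided by the square root of F. CPM are counts scaled by library total over the genes tested and by TMM factor, and log2 CPM used a prior count of 2. Lists were tested with camera in limma 3.58.1 on log2 CPM, with a preset inter-gene correlation of 0.01 and with an estimated one, and with fry. Single values per library were compared by a two-sided exact permutation test over 20 assignments, whose smallest possible p is 0.1.

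The 6 totals ranged from 4167784 to 4769157 estimated counts. In a library of this depth, 3 counts, the limit that a count of 0 allows, stand for 0.632 to 0.852 CPM. Such limits cover counting error only. How many reads were sequenced in all, and how many came from human RNA, is not given in the sources used here.

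Whether equal replicate numbers pair the tumours was checked by correlating, across genes, the deviations of libraries from their group means. Controls 1, 2 and 3 correlated with the same-numbered overexpression libraries at -0.09, -0.34 and -0.10, and pairs with different numbers gave -0.16 to 0.25. Deviations from the mean of 3 libraries are tied to each other, so these correlations cannot exclude a shared animal or day. The numbers were not treated as pairs because the labels do not say that they mark any, and a block by number was run as an alternative.

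The fit was tested on simulated data with the means, depths and fitted dispersions of these libraries and 200 genes changed. Among 12334 genes tested, 79% of the 100 genes changed 4-fold and 15% of the 100 changed 2-fold were recovered, and 14 of 108 calls were false. Genes were simulated independently of each other, unlike genes in a tumour. In the same kind of simulation a 1.5-fold rise of the G2M list gave a camera p of 4.0e-31.

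Alternatives set before the data were examined covered the test (DESeq2 1.42.0, limma-voom), the scaling, the filter on low counts, a block by replicate number, non-robust fitting, a test against a 1.5-fold change and leaving out each library. DESeq2 at its defaults took all rows with its own filtering, so it was also run on the genes edgeR tested, and limma-voom also without the filter. These 2 fits, restricting the test to genes above 0 in every library and weighting libraries by quality were added after seeing the data.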

Results

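RNA from 3 vector control and 3 HIF1A-AS3 overexpression A549 tumours grown in nude mice was quantified against mouse genes, 1 library per tumour. HIF1A-AS3 is an antisense RNA of the human HIF1A locus, which encodes the alpha subunit of the hypoxia-inducible transcription factor. Control libraries held 4236693, 4167784 and 4262778 estimated counts (replicates 1 to 3) and overexpression libraries 4769157, 4656226 and 4272525. No label says that the 3 tumours of a group came from separate mice, so p-values measure the spread between these tumours. No 2 libraries were duplicates: the closest pair, controls 1 and 3, differed by 3.96 times the sampling variance per gene.

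The comparison of overexpression with control tumours asked how raising HIF1A-AS3 in the tumour cells altered expression, here as seen on mouse genes. Of 12637 genes tested, 2 passed the threshold, 1 higher and 1 lower in overexpression tumours. The gene with ID ENSMUSG00000068964.6 was at 0 estimated counts in all 3 control libraries and at 96.3, 163 and 113 in overexpression replicates 1, 2 and 3. Its level was 29.2 ± 4.50 CPM (SD, n = 3) in overexpression tumours, at least 44.4-fold higher than 3 counts in each control library would give. The gene with ID ENSMUSG00000079224.6 showed the opposite pattern, with 165, 177 and 145 estimated counts in controls 1, 2 and 3 and 0 in all 3 overexpression libraries. It stood at 35.6 ± 4.44 CPM (SD, n = 3) in controls and was at least 49.2-fold lower in overexpression tumours by the same floor of 3 counts per library.

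Both genes had an adjusted p of 0.012 (edgeR quasi-likelihood test, Benjamini-Hochberg). With a block by replicate number in the same test neither passed, at an adjusted p of 0.11 for both. Each was at exactly 0 throughout one group and had non-whole estimates in the other, so restricting the test to genes above 0 in every library removes both by construction. No further gene passed with edgeR under that restriction, where 894 had an unadjusted p below 0.05. On the same filtered genes limma-voom called 7, of which 0 were above 0 in every library, and DESeq2 called 28, of which 18 were. The count of 2 moved with single libraries. Leaving out each library in turn gave fitted log2 fold changes of 9.85 to 10.09 for ENSMUSG00000068964.6 and -10.36 to -10.19 for ENSMUSG00000079224.6. These values could hardly move: with 1 group at 0 they depend on the prior count, here edgeR's default and not the 2 used for log2 CPM. With limma-voom they were 8.06 and -8.21. In edgeR the count was 0 without control replicate 1 (327 genes at an unadjusted p below 0.05), 0 without overexpression replicate 3 (947 genes), 1 without overexpression replicate 1 and 14 without overexpression replicate 2.

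Among genes above 0 in every library, the smallest p for a higher level belonged to ENSMUSG00000045545.9. It measured 132 ± 11.7 CPM in controls and 308 ± 44.1 CPM in overexpression tumours (SD, n = 3 each), a log2 fold change of 1.22 with a standard error of 0.18 and an adjusted p of 0.27 in edgeR. The smallest p for a lower level belonged to ENSMUSG00000039899.6, at 52.5 ± 19.5 CPM in controls and 8.0 ± 2.51 CPM in overexpression tumours (SD, n = 3 each). Its log2 fold change was -2.71 with a standard error of 0.36 and an adjusted p of 0.20 in edgeR. For both genes the 3 libraries of each group lay apart from the 3 of the other, which choosing genes by the smallest p favours. Neither passed the threshold in edgeR with the filter on low counts. Without that filter both did, at adjusted p values of 0.035 and 0.00013 in edgeR. On the filtered genes both passed with DESeq2, at adjusted p values of 8.6e-06 for ENSMUSG00000045545.9 and 3.8e-08 for ENSMUSG00000039899.6, and neither passed with limma-voom, at 0.23 each. Over 20 alternatives the adjusted p ranged from 5.3e-06 to 1.00 for the first and from 3.8e-08 to 0.64 for the second.

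**Figure D1:**
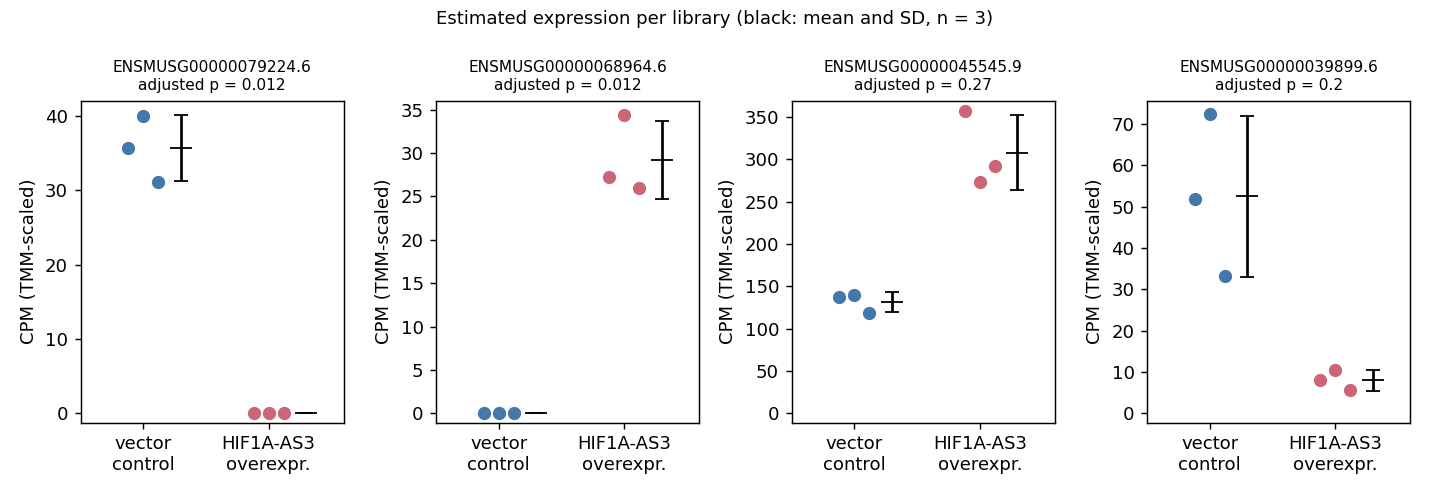
TMM-scaled CPM (y axis, linear) of 4 genes given by Ensembl ID in each vector control and HIF1A-AS3 overexpression library (points, replicates 1 to 3 from left to right), with the group mean and SD in black. The first and second genes are at 0 in every library of one group, and the other two are above 0 in all 6 libraries without passing the threshold in edgeR with the filter on low counts.

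Across all genes tested, 795 had an unadjusted p below 0.05 in edgeR, where chance would give 632 if genes were independent. Of these 795, 452 were higher and 343 lower in overexpression tumours. Scaling by library totals alone lowered the median log2 fold change of all genes by 0.22 and turned this split to 114 higher and 585 lower, and of the 4 genes it called 1 was higher and 3 were lower. The groups did not overlap in 1662 genes, or 13.2%, where chance gives 10% on average over groupings of 3 against 3. Genes vary together, so neither 632 nor 10% tells how far a single grouping can depart by chance. Other groupings of the 6 libraries gave 112 to 453 genes at an unadjusted p below 0.05 in edgeR. The exception was controls 1 and 3 with overexpression replicate 2 against the rest, at 2579. The median standard error of a log2 fold change was 0.28. A change smaller than about 1.57-fold, the median half-width of the 95% interval, could not be told from none in the typical gene. That interval is for a single gene and is not adjusted for the number of genes tested. Larger changes could be missed too, since 15% of 2-fold changes were recovered in the simulation with the fitted dispersions.

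No list of cell cycle genes passed the test between the groups. The lists were read on mouse genes, so they describe host cells plus any human RNA counted there, and not cycling of the A549 cells. The G2M list, genes assigned to the phase around mitosis, had a median log2 fold change of -0.11 over 168 genes tested. The S list, genes assigned to DNA replication, had a median of -0.08 over 193 genes, and the G1 list one of -0.04 over 234 genes. Over all genes the median was -0.01 on the same log2 CPM scale. In the edgeR fit 63 G2M genes had a positive and 105 a negative log2 fold change. With only genes that were never the lower member of a pair, the medians were -0.065 for G2M, -0.082 for S and -0.029 for G1. With library totals only, where the median over all genes was -0.25, the medians were -0.33 for G2M, -0.30 for S and -0.27 for G1, at adjusted p values of 0.12, 0.12 and 0.38. Camera gave adjusted p values of 0.20 for G2M, 0.20 for S and 0.71 for G1, and adjusted p = 0.58, 0.58 and 0.70 with an estimated correlation. In none of the 3 lists did a gene pass the threshold, either over all genes tested or adjusted over the list alone. At an unadjusted p below 0.05 in edgeR, 7 G2M genes, 8 S genes and 11 G1 genes were found. Fry, which asks whether a list moves one way on balance, gave p values of 0.13, 0.27 and 0.54 for G2M, S and G1, and 0.15, 0.26 and 0.33 for change in either direction.

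By library, the mean log2 CPM of the G2M genes lay 0.24, 0.04 and 0.09 below the control mean in overexpression replicates 1, 2 and 3. It was 4.48 ± 0.01 in controls and 4.35 ± 0.11 in overexpression tumours (SD, n = 3 each), with an exact two-sided permutation p of 0.1, the smallest this design allows. For the S genes the exact permutation p was 0.3 and for the G1 genes 0.5. Overexpression replicate 1, the library lowest in all 3 lists, also had the fewest genes with at least 1 count, 17356, against 18753 to 19010 in the other libraries.

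**Figure D2:**
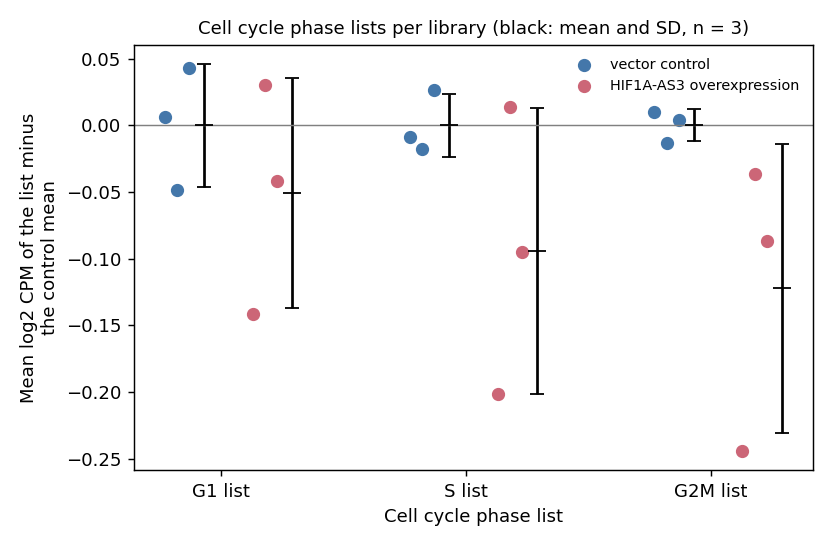
Mean log2 CPM of the genes of each cell cycle phase list minus the mean of the vector control libraries (y axis) for each list (x axis), with 1 point per library, replicates 1 to 3 from left to right, and the group mean and SD in black. All 3 overexpression libraries are below the 3 controls for the G2M list, replicate 1 furthest at 0.24 below the control mean, and overlap the controls for the S and G1 lists.

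The 3 overexpression tumours differed more from each other than the 3 control tumours did. The biological coefficient of variation, the spread between libraries beyond counting error, was 18.8% among controls and 36.4% among overexpression tumours. Leaving out any 1 library gave 12.2% to 24.8% for controls, and 33.2% to 40.2% for overexpression tumours. These ranges did not meet, but their values share libraries and do not measure the uncertainty of either spread. Another grouping of the 6 libraries gave a larger ratio of the 2 spreads, 2.07 against 1.94. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.941 to 0.964 between controls, 0.900 to 0.924 between overexpression tumours and 0.894 to 0.960 between groups. Overexpression replicate 2 had a mean r of 0.951 with the 3 controls and 0.908 with the other overexpression tumours. Overexpression replicate 3 had a mean r of 0.923 with the controls and 0.920 with its own group, and replicate 1 one of 0.903 and 0.912.

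Counts were also spread less evenly over genes in 2 of the 3 overexpression tumours. The 20 most abundant genes held 15.7%, 11.3% and 12.8% of counts in overexpression replicates 1, 2 and 3, and 11.1%, 11.3% and 10.98% in controls 1, 2 and 3. The group means were 13.2% ± 2.25 and 11.1% ± 0.137 (SD, n = 3 each), with an exact two-sided permutation p of 0.1, the smallest possible. Without overexpression replicate 1 the difference between groups fell from 2.15 to 0.924 percentage points. Counts per library were higher in overexpression tumours by 343551 on average, also at the smallest exact permutation p of 0.1, and the number of genes with at least 1 count gave an exact permutation p of 0.2.

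**Figure D3:**
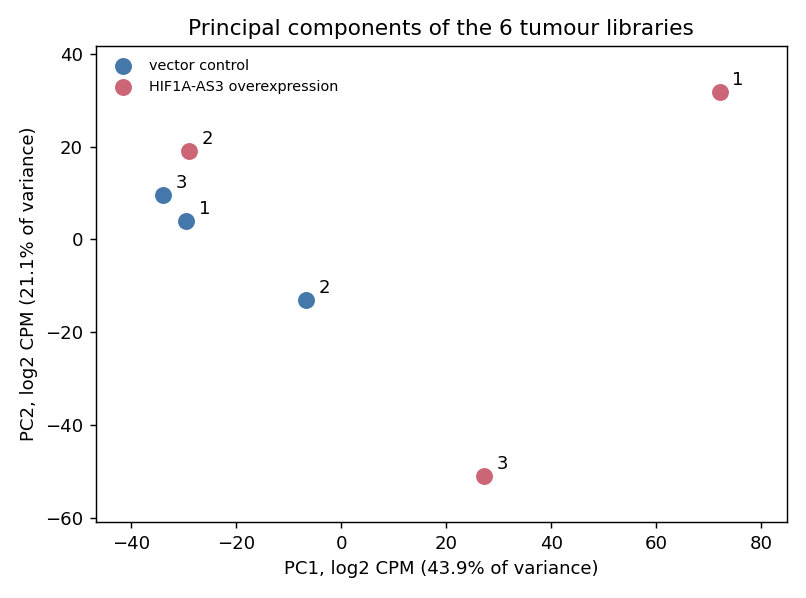
First and second principal components (x and y axes, log2 CPM units) of the 6 libraries over 12637 genes, with groups by colour and replicate numbers beside the points. Overexpression replicates 1 and 3 lie away from the other libraries, and overexpression replicate 2 lies beside controls 1 and 3.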

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

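The restriction to genes above 0 in every library, the quality weights, DESeq2 on the filtered genes, limma-voom without the filter, and the cell cycle lists with their settings were chosen after the data were seen. The number of genes changed, 2 in edgeR, was 29 with DESeq2 on all rows, 28 with DESeq2 on the genes edgeR tested, 7 with limma-voom on those genes, 17 with limma-voom and no filter, 4 with library totals only, 14 with no filter on low counts, 0 with a replicate block and 0 among genes above 0 in every library; leaving out 1 library at a time gave 0 to 14. DESeq2 size factors, the upper quartile, a mean of at least 5 CPM, robust fitting off and a test against a 1.5-fold change each gave the same 2 genes, and weighted limma-voom gave 3, these 2 included. Of the 28 DESeq2 calls on filtered genes, 10 were at 0 throughout one group, as were all 7 of limma-voom on those genes. The share of called genes that were higher, 50%, ranged from 0% to 33.3% with 1 library left out, the 0% without overexpression replicate 1. Over the 16 alternatives with a call it ranged from 0% to 66.7%, the highest with weighted limma-voom. It was 27.6% with DESeq2 on all rows and 28.6% with limma-voom on the filtered genes. The calls of ENSMUSG00000079224.6 and ENSMUSG00000068964.6 were lost under the replicate block (adjusted p 0.11 for both, log2 fold changes -10.29 and 10.00, as in the fit without it) and without control replicate 1 or overexpression replicate 3, and that of ENSMUSG00000068964.6 also without overexpression replicate 1, each with similar fitted fold changes. Same-numbered libraries did not correlate positively in the check of deviations, but that check cannot exclude pairing, so the block stays an alternative. Under the block 414 genes had an unadjusted p below 0.05 in edgeR. ENSMUSG00000045545.9 and ENSMUSG00000039899.6 passed the threshold with DESeq2 on either gene set and in edgeR with no filter on low counts, and the second also in limma-voom with no filter, with adjusted p values from 5.3e-06 to 1.00 and from 3.8e-08 to 0.64 over 20 alternatives each. None of the 3 cell cycle lists passed in any of 14 alternatives, the block included; the lowest adjusted p was 0.098, for G2M and S without overexpression replicate 2. Alternatives that need gene names (totals without mitochondrial, ribosomal and haemoglobin genes, rows with a symbol, symbol lists) were not run. In the simulation at this depth, 15% of 2-fold changes were recovered with the fitted dispersions and 86% with dispersions 0.1 times those, so the spread between libraries, which mixes tumour and library preparation, limited recovery there.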

Other observations

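The tests of depth by totals, of abundant genes and of the spread over splits were set down before their results were seen; the others below were chosen after.

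Exact zeros were found beside substantial counts in many genes. Of 9351 genes with at least 50 estimated counts in some library, 162 were at exactly 0 in at least 1 other, and in 78 of these a single library was at 0, which was overexpression replicate 1 for 36 genes and control replicate 2 for 17. Such zeros occurred in 2.02% of genes with a non-whole estimate and 0.364% of genes with estimates whole to within 0.001 in every library (odds ratio 5.65, 95% interval 2.53 to 15.7, Fisher's exact test p = 1.0e-07), and both genes called between the groups had non-whole estimates, as had 82.4% of the 9351, so that alone does not set them apart. The excess of zeros is consistent with a count estimator that gives reads shared by several genes wholly to one of them, a candidate explanation for the 2 calls; sequences of the mouse transcripts, not used here, would show whether each gene has a near-identical partner. Genes at 0 throughout one group and at 10 or more counts throughout the other numbered 11, and 2 of the 10 splits of the libraries gave as many, the highest other being 15, a design too small for a share under 0.05. An effect of HIF1A-AS3 on these genes, or a genetic difference between host mice, stays open as untested.

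The number of genes changed was 2 for the real split and 5 for the highest other, controls 1 and 3 with overexpression replicate 2 against the rest, so 2 of the 10 splits gave as many; 10 splits are too few for a share under 0.05. That split also had 2579 genes at an unadjusted p below 0.05, against 795 for the real one and 112 to 453 for the others. It was singled out as the highest of the 10 and groups the libraries already seen to lie together. It thus restates the closeness of overexpression replicate 2 to controls 1 and 3. A swap of overexpression replicate 2 with control replicate 2 would give this same grouping, and the comparison cannot tell the swap from such closeness. The ratio of the spreads within the 2 groups was 1.94 for the real split and 2.07 for the same other split, again 2 of 10. For the cell cycle lists the smallest camera p was 0.065 for the real split, 1 of 10 as small, and 0.101 for the next.

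Overexpression replicate 1 was the library least like the rest, with a mean r of 0.906 against 0.922 for the next lowest, a gap of 0.0153. Effective depth is the total over the genes tested times the TMM factor. Thinning all libraries to the smallest total left a gap of 0.0162 (SD 0.000154 over 20 thinnings). That decides nothing, since this library had the largest total but the smallest effective depth, 3520834, and the thinning lowered it further. A smaller effective depth alone is argued against: with all libraries thinned to that depth the gap was 0.0149 (SD 0.0018 over 100 resamplings of genes). The gap was not confined to the 500 most abundant genes, being 0.0214 (SD 0.0019 over 100 resamplings of genes) without them. Leaving them out narrows the range of expression, which can by itself lower correlations and widen the gap, so its rise is not interpreted. That removal leaves genes with lower counts and was not combined with thinning, so it cannot tell whether depth widened the gap. SDs over resampled genes do not measure the spread between tumours. RNA quality, the share of human reads counted on mouse genes, another makeup of host cells and a response to HIF1A-AS3 in that tumour stay open and were not tested, because they need gene names or read data.

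Overexpression replicate 2 was closer to the controls than to its own group. A swap with a control library stays open. A swap with control replicate 2 would give the split above that had 5 genes changed, against 2 for the real one. Overexpression replicate 3 was closest to control replicate 2 (r 0.931), while control replicate 2 was closest to control replicate 1 (r 0.954). Each control was closer to the other controls and overexpression replicate 2 than to overexpression replicates 1 and 3, the smallest difference in mean r being 0.0211 (SD 0.0022 over 100 resamplings of genes), but the measure did not place both overexpression tumours it was checked on. Overexpression replicate 1 was closer to replicate 3 than to the remaining libraries by 0.0220 (SD 0.0024). Replicate 3 was closer to replicate 1 by only 0.0029 (SD 0.0025), which is within the 2 SD taken as the limit. Neither can a single wrong label, or little HIF1A-AS3 in that tumour, be told apart from a tumour whose host tissue did not differ, since 0 rows carried a human gene ID that could hold the overexpressed RNA. Without this library 14 genes passed the threshold, and 2659 had an unadjusted p below 0.05; leaving it out is an alternative and not a corrected result.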
